A study of Mus musculus with 60 samples.

How the data were processed

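Tissue was prefrontal cortex, libraries were made with the TruSeq Stranded mRNA kit, and each library came from 1 of 12 groups of 5, per the labels. Per the submitters' processing notes the genome was GRCm38, and Salmon 0.11.2, R 3.6.0 and DESeq2 1.19.11 were named without stating which step each served. Per the file headers there was 1 column per library and 60 columns, and replicates were not pooled. The deposited values were treated as a signal made by the authors by dividing gene counts by 1 size factor per library. From the values, each column was a whole multiple of 1 step, so whole reads could be recovered. The share of recovered values within 0.05 of a whole number was 1 in the deposited columns. In 4 columns the step lay within 1% of 1, where this check cannot tell recovered reads from rounded values. Size factors ran from 0.796 to 1.25 and deposited column totals from 27.2 to 30.7 M, computed from the file. The share of signal from mitochondrial genes ran from 6.47% to 10.6%, computed from the file. Over 120 pairs of replicates the squared difference divided by that expected from counting reads ran from 2.93 to 67.1 on average per gene, so libraries of a group differed by more than counting error.

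Of 18088 gene identifiers, 18077 matched a symbol in GENCODE vM21 (GRCm38), 20 symbols occurred more than once, and 5 genes were 0 in every library. How the authors filtered genes was not stated in the labels. Litters were not named in the labels, and each drug reached the pups through the dam, so p measures the spread between libraries and not between litters.

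Values were analysed as log2(signal + 1). Genes with a mean of at least 10 over all libraries were kept, leaving 16659. limma 3.58.1 in R 4.3.3 fitted 12 group means with a mean-variance trend and robust moderation, and contrasts compared averages of group means. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 within its contrast. edgeR 4.0.16 on the recovered reads called 5278 genes for genotype in vehicle, against 5210 with limma. Other packages were statmod 1.5.0, data.table (version 1.17.8), pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 under Python 3.11.15.

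Gene lists were tested with camera in limma with a preset correlation of 0.01 between genes, adjusted over the lists of a contrast, and again with the correlation estimated from the data. Of 177 list calls over the 9 contrasts averaged over sex, 6 kept the call with an estimated correlation. The lists held 1362 symbols, of which 1319 were tested. Numbers of list members passing were counted in 2 ways: after adjustment over all tested genes, and adjusted over the list alone.

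Genes were named by rule. For each contrast averaged over sex these were the 10 highest and 10 lowest fold changes among called genes with a mean signal of at least 50 and the same direction in both sexes. For interactions they were the 5 smallest p in each direction, and for gene lists with a call up to 4 members with the smallest p. Models without a gene symbol were counted but not named. Contrasts, thresholds, lists and naming rules were chosen before the data were examined. The marker score covariates, the exclusion of libraries that stand apart, the neuron-share comparison, the criteria of the olfactory tests and the restriction of Pten effects to contrasts averaged over sex were chosen after seeing the data.

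The code was tested on simulated data with 50 genes changed at each of 4 folds in the genotype contrast in vehicle. limma called 27 at 1.25-fold, 37 at 1.5-fold, 49 at 2-fold and 49 at 3-fold in the right direction, with 7 unchanged genes called. The genes were changed in both sexes, and in the contrast within females limma called 20, 33, 47 and 49, with 7 unchanged genes called. In the contrast averaged over sex edgeR called 27, 39, 49 and 49, with 8. Contrasts without any simulated change had 0 genes called. Simulated genes varied independently, without an axis along which many genes move together between libraries. These counts therefore test the code and do not measure false calls in the real libraries.

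For splits, the libraries of the compared groups were divided again within sex into groups of 5, with 100 splits including the real one. Called genes were counted in each split with limma as in the real contrast. Alternatives were quantile normalization, edgeR, no gene filter, a pseudocount of 5, array weights, a replicate block, a fit of only the compared libraries, leaving out 1 library at a time, leaving out libraries that stand apart, and olfactory scores as covariates. Trends on GC content and transcript length were removed for 16648 genes with a known GC content, and log2 recovered reads were used as a depth covariate.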

Results

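Prefrontal cortex of C57BL/6J mice at postnatal day 25 was sequenced from 60 libraries in 12 groups of 5. The groups crossed a heterozygous Pten knock-in (HT) or wild type (WT), vehicle, fluoxetine or lithium given through maternal milk from postnatal day 3 to 24, and both sexes. The file held 18088 genes in the deposited DESeq-normalized signal, and 16659 genes with a mean of at least 10 were tested with limma. Recovered reads ran from 23.6 to 35.1 M per library with a median of 32.2 M. Genes above 0 ran from 17976 to 18051. Xist, the X-inactivation transcript, was 17713 to 32750 in female libraries and at most 129.62 in male ones. Ddx3y, encoded on the Y chromosome, was at most 30.6 in female libraries and at least 1465 in male ones. Differences below are log2 fold changes ± standard error between group means averaged over sex, with 10 libraries on each side, and adjusted p values are from limma.

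Pten itself (ENSMUSG00000013663, chromosome 19, 32757497 to 32826160, plus strand) was slightly higher in HT. Pten, the lipid phosphatase that opposes PI3K signalling, was 7485 ± 182 (mean ± SD, n = 5) in HT vehicle females against 6809 ± 207 in WT vehicle females. The male vehicle groups were 7286 ± 313 in HT and 6591 ± 403 in WT. Under fluoxetine the female groups were 7396 ± 85.5 in HT and 6872 ± 483 in WT, and the male groups 7475 ± 316 and 7026 ± 626. Lithium groups were 7556 ± 184 in HT females, 7638 ± 103 in HT males, 7171 ± 342 in WT females and 6978 ± 451 in WT males. Averaged over sex, Pten was higher in HT by 0.14 ± 0.03 in vehicle (adjusted p = 0.00105) and by 0.10 ± 0.03 under fluoxetine (adjusted p = 0.0323). The difference under lithium, 0.10 ± 0.03, did not pass (adjusted p = 0.0915). No drug effect on Pten passed: fluoxetine gave 0.05 ± 0.03 (adjusted p = 0.427) in WT and 0.01 ± 0.03 (adjusted p = 0.863) in HT, and lithium 0.08 ± 0.03 (adjusted p = 0.170) and 0.04 ± 0.03 (adjusted p = 0.430).

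**Figure D1:**
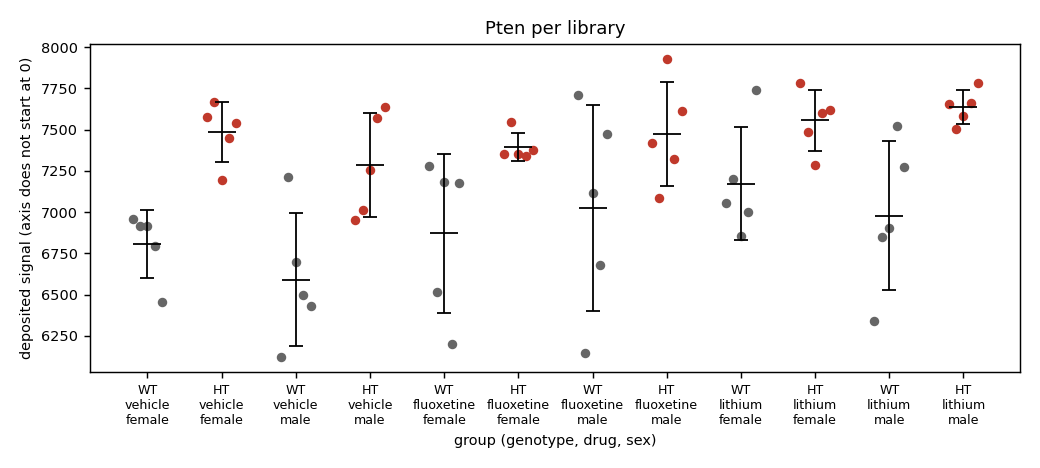
Deposited Pten signal in each library of the 12 groups, spread sideways for legibility. Horizontal bars are means, error bars are standard deviations, grey is WT and red is HT, and the vertical axis starts above 0.

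Markers of the olfactory bulb and anterior olfactory nucleus, regions next to the dissected cortex, varied more between libraries than any other region's markers. Their mean log2(signal + 1) was 9.72 ± 0.45 (SD, n = 10) in HT vehicle and 7.63 ± 1.97 in WT vehicle. The other arms were 8.38 ± 0.93 in HT fluoxetine, 8.24 ± 1.72 in HT lithium, 8.35 ± 1.89 in WT fluoxetine and 8.34 ± 1.63 in WT lithium. Single libraries ran from 5.62 to 8.22 in WT vehicle females and from 9.02 to 10.13 in HT vehicle females. The male vehicle groups overlapped, with 5.88 to 10.41 in WT and 9.43 to 10.46 in HT. Cdhr1, a cadherin of mitral and tufted cells, was 3034 ± 1106 in HT vehicle and 1250.1 ± 1689 in WT vehicle, and the mitral cell transcription factor Eomes was 539 ± 207 and 222 ± 299.9.

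**Figure D2:**
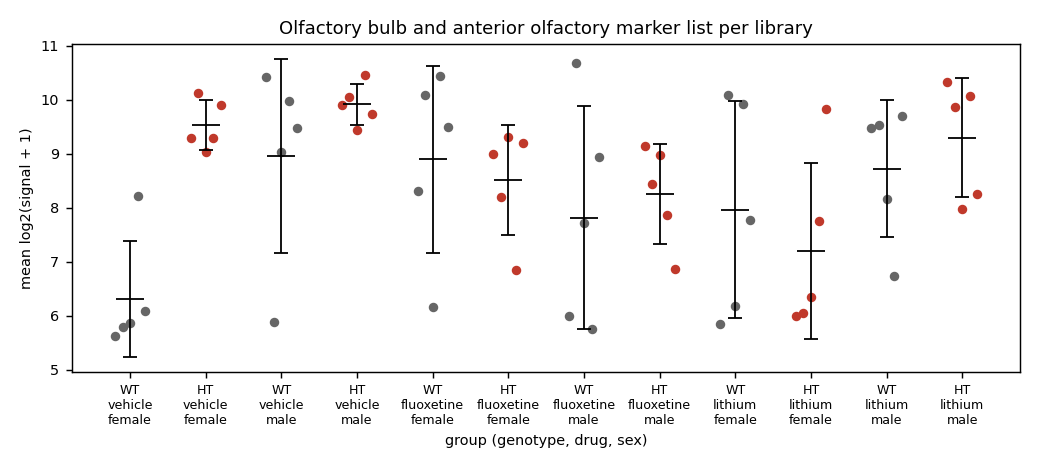
Mean log2(signal + 1) of the olfactory bulb and anterior olfactory nucleus marker list in each library, by group. Points are libraries spread sideways, bars are means, error bars are standard deviations, grey is WT and red is HT.

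In vehicle, HT cortex carried more transcripts of oligodendrocytes, the myelin-forming cells, than WT cortex. Plp1, a main protein of compact myelin (X chromosome, 136822671 to 136839733), averaged 58407 ± 8575 in HT and 29750 ± 13629 in WT (mean ± SD, n = 10). Genes higher in HT were Gsn (0.88 ± 0.13), Ugt8a (1.03 ± 0.17), Myrf (0.96 ± 0.16) and Gjc2 (0.96 ± 0.16) among mature oligodendrocyte genes, Enpp6 (0.93 ± 0.15), Sirt2 (0.37 ± 0.07), Gpr17 (0.34 ± 0.06) and Bcas1 (0.74 ± 0.14) among newly formed ones and Sox10 (0.66 ± 0.11), Ptprz1 (0.38 ± 0.06), Olig2 (0.47 ± 0.09) and Chst3 (0.56 ± 0.10) among precursor genes. Of 30 mature oligodendrocyte genes 28 were higher and 0 lower (28 adjusted over the list alone), with a median of 0.93 (adjusted p = 5.99e-18, but adjusted p = 0.345 with an estimated correlation). Newly formed oligodendrocyte genes had 15 of 19 higher (15 adjusted over the list alone; adjusted p = 5.95e-09, but adjusted p = 0.289 with an estimated correlation). Precursor genes had 11 of 18 higher and 1 lower (13 and 1 adjusted over the list alone; adjusted p = 9.57e-06, but adjusted p = 0.289 with an estimated correlation). A list named for perineuronal nets, the matrix around fast-spiking neurons, had 6 of 10 genes higher (7 adjusted over the list alone), with Ncan (0.31 ± 0.04), Acan (0.90 ± 0.21) and Hapln2 (0.94 ± 0.23) (adjusted p = 0.00150, but adjusted p = 0.157 with an estimated correlation). Its genes are not all particular to such nets, and which cells expressed them was not tested.

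**Figure D3:**
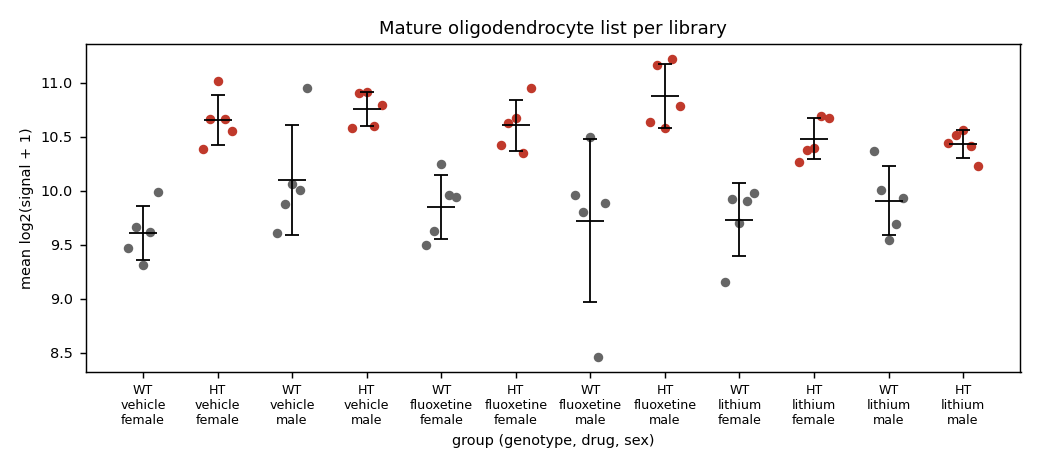
Mean log2(signal + 1) of the mature oligodendrocyte gene list in each library, by group. Points are libraries spread sideways, bars are means, error bars are standard deviations, grey is WT and red is HT.

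The largest rises in HT vehicle were olfactory genes: Ms4a15 (3.93 ± 1.13), Eomes (3.79 ± 1.08), Cdhr1 (3.34 ± 0.89), Tbx21 (3.25 ± 1.02) and Doc2g (3.02 ± 0.94). Next came Omp (2.99 ± 0.81), Dnah11 (2.95 ± 0.92), Shisa3 (2.89 ± 0.85), Scgn (2.84 ± 0.97) and Frmd7 (2.82 ± 0.91). Of 18 olfactory markers 16 were higher (17 adjusted over the list alone), with a median of 2.18 (adjusted p = 6.88e-07, but adjusted p = 0.459 with an estimated correlation). Cell-cycle and migrating neuroblast genes moved with them, with Top2a (1.08 ± 0.20), Mki67 (1.001 ± 0.19) and Cdk1 (0.89 ± 0.25) and 8 of 19 higher (13 adjusted over the list alone; adjusted p = 6.59e-04, but adjusted p = 0.408 with an estimated correlation). So did markers of septum and basal forebrain, Nts (2.03 ± 0.44) and Ngfr (0.87 ± 0.22) (adjusted p = 0.00699, but adjusted p = 0.399 with an estimated correlation), and of thalamus and hypothalamus, Plekhg1 (0.51 ± 0.08) and Calb2 (1.89 ± 0.58) (adjusted p = 0.0443, but adjusted p = 0.503 with an estimated correlation). With the olfactory score as a covariate Tbx21 (-0.14), Doc2g (-0.14), Dnah11 (-0.092), Scgn (-0.39), Frmd7 (-0.20) and Calb2 (-0.039) turned direction. The lowest genes in HT were Ttr (-2.28 ± 0.78), Col6a4 (-0.83 ± 0.21), Car13 (-0.80 ± 0.17), Spag5 (-0.80 ± 0.10) and Etnk2 (-0.78 ± 0.12). Next were Rspo1 (-0.78 ± 0.17), Igfn1 (-0.78 ± 0.15), Tnfrsf25 (-0.78 ± 0.15), Olfr78 (-0.76 ± 0.14) and Myoc (-0.76 ± 0.13). Ttr, the thyroxine carrier made in choroid plexus, was 28.8 ± 16.6 in HT and 197 ± 244 in WT.

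Many genes for protein synthesis and respiration were lower in HT vehicle. Ribosomal protein genes Rps14 (-0.25 ± 0.04), Rpl38 (-0.27 ± 0.05), Rps21 (-0.35 ± 0.06) and Rpl26 (-0.28 ± 0.05) were lower, as were 45 of 79 of their list with 1 higher (48 and 1 adjusted over the list alone; adjusted p = 1.99e-11, but adjusted p = 0.471 with an estimated correlation). Respiratory chain genes Cox6c (-0.42 ± 0.06), Cox8a (-0.35 ± 0.06), Ndufc2 (-0.27 ± 0.05) and Cox7a2 (-0.29 ± 0.05) were lower, with 35 of 75 lower and 3 higher (35 and 3 adjusted over the list alone; adjusted p = 1.11e-07, but adjusted p = 0.466 with an estimated correlation). Mitochondrially encoded genes were lower under the deposited scaling, including mt-Nd2 (-0.29 ± 0.06), mt-Cytb (-0.26 ± 0.05) and mt-Nd1 (-0.23 ± 0.05) (adjusted p = 7.73e-05, but adjusted p = 0.408 with an estimated correlation), but after quantile normalization these 3 were 0.00, 0.03 and 0.11. A list named for chromatin regulators and long genes was higher, with Arid1b (0.26 ± 0.04), Brd4 (0.27 ± 0.04), Chd4 (0.21 ± 0.04) and Prrc2a (0.26 ± 0.05) and 32 of 41 higher against 1 lower (35 and 1 adjusted over the list alone; adjusted p = 1.81e-13, but adjusted p = 0.399 with an estimated correlation). Trends on GC content and transcript length were removed only for the count of all genes. Whether the ribosomal, respiratory chain and long gene shifts stay without those trends was not tested. Deep-layer neuron genes Bcl11b (0.68 ± 0.13), Bcl6 (0.34 ± 0.08) and Nxph4 (2.06 ± 0.50) were higher (adjusted p = 0.00150, but adjusted p = 0.408 with an estimated correlation), and upper-layer genes Calb1 (-0.39 ± 0.08), Otof (-0.53 ± 0.11), Rasgrf2 (-0.31 ± 0.07) and Lamp5 (-0.42 ± 0.10) were lower (adjusted p = 0.00849, but adjusted p = 0.408 with an estimated correlation). Matrix genes Lamc1 (0.31 ± 0.04), Hspg2 (0.50 ± 0.07), Col4a1 (0.29 ± 0.06) and Col18a1 (0.48 ± 0.10) were higher (adjusted p = 9.57e-06, but adjusted p = 0.408 with an estimated correlation). In all, 2729 genes were higher and 2481 lower in HT vehicle, and edgeR on the recovered reads called 5278. After quantile normalization 2589 were higher and 3020 lower, so the balance turned. With the olfactory marker score as a covariate, chosen after seeing the data, 2519 of the 5210 genes still passed and 1951 others did, 4470 in all. With a linear score 5762 passed, of which 3581 were among the 5210.

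Under fluoxetine, oligodendrocyte genes again separated HT from WT, and the mean olfactory score differed by 0.03. The highest genes were Ndst4 (1.84 ± 0.49), Tfap2d (1.57 ± 0.54), Ppp1r14a (1.46 ± 0.22), Nipal4 (1.45 ± 0.21) and Nmbr (1.39 ± 0.44). Next were Abi3bp (1.37 ± 0.42), Fa2h (1.35 ± 0.21), Gjb1 (1.31 ± 0.22), Nkx6-2 (1.24 ± 0.21) and Ugt8a (1.21 ± 0.17). Mature oligodendrocyte genes had 27 of 30 higher (28 adjusted over the list alone) and a median of 1.10, including Cnp (0.94 ± 0.14) and Gjc2 (1.10 ± 0.16) (adjusted p = 1.67e-32, but adjusted p = 0.0568 with an estimated correlation). Newly formed oligodendrocyte genes had 14 of 19 higher (16 adjusted over the list alone; adjusted p = 8.63e-15, but adjusted p = 0.0568 with an estimated correlation). Precursor genes Cspg4 (0.51 ± 0.06), Olig1 (0.51 ± 0.08) and Olig2 (0.55 ± 0.09) were higher (adjusted p = 2.61e-07, but adjusted p = 0.0568 with an estimated correlation). Cholesterol-related genes Ldlr (0.66 ± 0.09), Cyp51 (0.35 ± 0.05), Dhcr7 (0.18 ± 0.03) and Hmgcs1 (0.37 ± 0.07) were higher, as were 19 of 25 of their list (22 adjusted over the list alone; adjusted p = 3.09e-17, but adjusted p = 0.0918 with an estimated correlation). Microglial genes Itgam (0.54 ± 0.07), Cx3cr1 (0.34 ± 0.06) and Csf1r (0.20 ± 0.04) were higher (adjusted p = 4.86e-07, but adjusted p = 0.450 with an estimated correlation). In the perineuronal net list Ncan (0.28 ± 0.04), Bcan (0.17 ± 0.04), Hapln2 (0.89 ± 0.23) and Has3 (0.39 ± 0.11) were higher too (adjusted p = 7.58e-05, and adjusted p = 0.0229 with an estimated correlation). Striatal markers had 3 of 19 higher (3 adjusted over the list alone) and a median of 0.30 (adjusted p = 0.0240, but adjusted p = 0.616 with an estimated correlation). Deep-layer genes had 4 of 19 higher (6 adjusted over the list alone) and a median of 0.25 (adjusted p = 0.00546, but adjusted p = 0.513 with an estimated correlation). HT fluoxetine male replicates 4 and 2 had the highest means of their arm in striatal markers (9.62 and 8.84) and in mature oligodendrocyte genes (11.22 and 11.17).

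The lowest genes in HT under fluoxetine were Kl (-0.81 ± 0.28), Etnppl (-0.75 ± 0.24), Sult1a1 (-0.74 ± 0.12), Pkp2 (-0.73 ± 0.14) and Angptl4 (-0.68 ± 0.17). Next were Cd163 (-0.63 ± 0.14), Car13 (-0.62 ± 0.17), Aldh3b2 (-0.60 ± 0.12), Xdh (-0.59 ± 0.17) and Zfp97 (-0.57 ± 0.10). Activity-induced genes Nr4a3 (0.78 ± 0.13), Per1 (0.34 ± 0.06), Klf10 (0.59 ± 0.11) and Arc (0.85 ± 0.18) were higher, with 11 of 30 immediate early genes higher (17 higher and 1 lower adjusted over the list alone; adjusted p = 2.61e-07, but adjusted p = 0.260 with an estimated correlation). Ribosomal protein genes Rpl4 (-0.12 ± 0.02), Rps3a1 (-0.24 ± 0.05) and Rpl17 (-0.25 ± 0.06) were lower, as were 22 of 79 of the list (51 adjusted over the list alone; adjusted p = 1.09e-14, but adjusted p = 0.498 with an estimated correlation). Proteasome genes Psma6 (-0.24 ± 0.04), Psma2 (-0.18 ± 0.04) and Psma3 (-0.16 ± 0.03) were lower (adjusted p = 4.99e-07, but adjusted p = 0.296 with an estimated correlation). In total 1283 genes were higher and 964 lower, edgeR called 2272, and with the olfactory score as a covariate 3646 passed. Fitting only the compared libraries called 1264, and leaving out 1 library gave 1654 to 2659.

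Under lithium many of the genes highest in HT were myelin genes. The highest were Ppp1r14a (0.98 ± 0.22), Fa2h (0.88 ± 0.21), Nipal4 (0.86 ± 0.21), Mog (0.83 ± 0.19) and Arc (0.82 ± 0.18). Next were Mal (0.81 ± 0.21), Plp1 (0.80 ± 0.19), Ugt8a (0.80 ± 0.17), Nkx6-2 (0.78 ± 0.21) and Prr5l (0.75 ± 0.15). Plp1 averaged 47374 ± 5489 in HT lithium and 27864 ± 7272 in WT lithium. Mature oligodendrocyte genes had 20 of 30 higher (28 adjusted over the list alone) and a median of 0.69 (adjusted p = 3.88e-32, but adjusted p = 0.0966 with an estimated correlation). Precursor genes Olig2 (0.43 ± 0.09), Olig1 (0.32 ± 0.08) and Neu4 (0.24 ± 0.06) were higher (adjusted p = 4.26e-05, but adjusted p = 0.181 with an estimated correlation), and Ncan (0.21 ± 0.04) led the perineuronal net list (adjusted p = 4.16e-05, and adjusted p = 0.00918 with an estimated correlation). The clock genes Nr1d1 (0.33 ± 0.06) and Ciart (0.34 ± 0.07) and the activity-induced gene Dusp1 (0.49 ± 0.11) were also higher. The clock list as a whole averaged 10.33 ± 0.06 (SD, n = 10) in HT lithium and 10.29 ± 0.06 in WT lithium. The lowest genes were Gli1 (-0.69 ± 0.17), Prg4 (-0.52 ± 0.13), Rmst (-0.46 ± 0.12), Scn7a (-0.43 ± 0.11) and Lepr (-0.37 ± 0.09). Next were Cd83 (-0.33 ± 0.09), Ccpg1os (-0.31 ± 0.08), Zfp825 (-0.28 ± 0.07), Zfp937 (-0.28 ± 0.08) and Spin2c (-0.27 ± 0.07). In total 129 genes were higher and 78 lower, edgeR called 210, and the olfactory score differed by -0.10. The count ran from 79 to 263 on leaving out 1 library, and was 593 with array weights, 664 with the olfactory score as a covariate and 1269 with a linear score. Across vehicle, fluoxetine and lithium, 93 genes were higher in HT each time and 19 lower each time.

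In WT mice, fluoxetine raised Fkbp5 and many genes of endoplasmic reticulum (ER) folding and lowered some activity-induced genes. Fkbp5, a co-chaperone of the glucocorticoid receptor (chromosome 17, 28399094 to 28517527), went from 679.8 ± 84.5 to 1541 ± 212, a change of 1.18 ± 0.09 (adjusted p = 2.48e-13). The other highest genes were Hif3a (1.09 ± 0.13), Pkp2 (0.96 ± 0.14), Map3k6 (0.89 ± 0.13), Zbtb16 (0.87 ± 0.10) and Paqr5 (0.61 ± 0.10). Next were Sdf2l1 (0.60 ± 0.08), Smim3 (0.57 ± 0.11), Lrfn2 (0.55 ± 0.09) and Sult1a1 (0.53 ± 0.12). ER chaperone and folding genes Manf (0.32 ± 0.04), Pdia6 (0.32 ± 0.04) and Calr (0.27 ± 0.04) rose, as did 16 of 22 of their list with 0 lower (18 and 0 adjusted over the list alone; adjusted p = 3.75e-26, and adjusted p = 0.00189 with an estimated correlation). Arc, a synaptic plasticity gene, fell from 5612 ± 1142 to 2285 ± 897, or -1.36 ± 0.18 (adjusted p = 1.19e-06). Next lowest were Egr2 (-1.27 ± 0.20), Tnfsf10 (-1.03 ± 0.13), Junb (-0.999 ± 0.12), Gbp4 (-0.99 ± 0.15) and Fos (-0.97 ± 0.16). Next were Dusp1 (-0.91 ± 0.11), Tnfrsf25 (-0.87 ± 0.15), Nr4a1 (-0.87 ± 0.11) and Btg2 (-0.78 ± 0.15). Immediate early genes had 18 of 30 lower and 1 higher (20 and 1 adjusted over the list alone), with a median of -0.54 (adjusted p = 2.00e-22, and adjusted p = 0.0137 with an estimated correlation). Cholesterol-related genes Insig1 (-0.41 ± 0.05), Ldlr (-0.52 ± 0.09), Stard4 (-0.27 ± 0.06) and Msmo1 (-0.27 ± 0.07) fell (adjusted p = 8.83e-12, but adjusted p = 0.225 with an estimated correlation). Endothelial genes Tek (-0.57 ± 0.06), Slco1a4 (-0.43 ± 0.05), Tie1 (-0.24 ± 0.05) and Cdh5 (-0.30 ± 0.07) fell (adjusted p = 2.31e-09, but adjusted p = 0.216 with an estimated correlation). In total 468 genes were higher and 529 lower, and edgeR called 926. Fitting only the compared libraries called 349, and leaving out 1 library gave 681 to 1420. Olfactory markers had a median of 0.78 with 0 of 18 passing, and 2206 genes passed with their score as a covariate. The balance turned with that score (1175 higher, 1031 lower), with a linear score (1696, 1232) and with array weights (1024, 978).

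**Figure D4:**
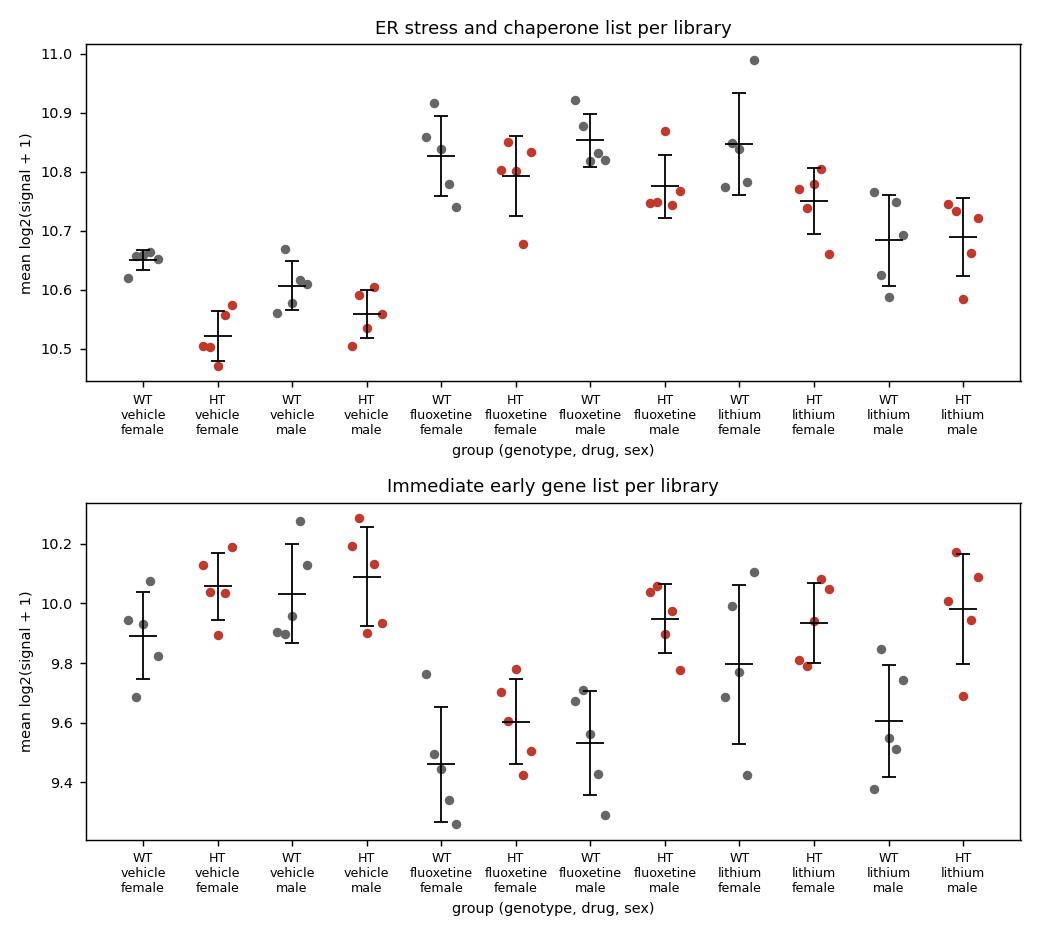
Mean log2(signal + 1) of the ER stress and chaperone list and of the immediate early list in each library, by group. Points are libraries spread sideways, bars are means, error bars are standard deviations, grey is WT and red is HT.

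In HT mice fluoxetine also raised many ER genes and lowered some immediate early genes. The highest genes were Map3k6 (0.88 ± 0.13), Serinc2 (0.81 ± 0.18), Pkp2 (0.77 ± 0.14), Sdf2l1 (0.75 ± 0.08) and Mc4r (0.72 ± 0.19). Next were Hif3a (0.67 ± 0.13), Zbtb16 (0.66 ± 0.10), Cys1 (0.63 ± 0.10), Smim3 (0.58 ± 0.11) and Serpinb8 (0.58 ± 0.13). Hspa5, the main ER chaperone, went from 5434 ± 446 to 7974 ± 783 (0.55 ± 0.06), beside Pdia6 (0.41 ± 0.04) and Calr (0.32 ± 0.04). ER genes had 16 of 22 higher and 0 lower (17 and 0 adjusted over the list alone; adjusted p = 7.80e-24, and adjusted p = 0.00372 with an estimated correlation). Cytosolic chaperones Chordc1 (0.20 ± 0.04), Hspa1b (0.53 ± 0.15) and Hsph1 (0.22 ± 0.07) also rose (adjusted p = 7.29e-05, but adjusted p = 0.753 with an estimated correlation). The lowest genes were Clca3a1 (-1.18 ± 0.37), Fosb (-1.12 ± 0.19), Npas4 (-1.02 ± 0.19), Map3k1 (-0.96 ± 0.30) and Fos (-0.96 ± 0.16). Next were Otop2 (-0.94 ± 0.31), Btg2 (-0.85 ± 0.15), Capn6 (-0.84 ± 0.24), Filip1l (-0.82 ± 0.25) and Gem (-0.71 ± 0.21). Immediate early genes had 13 of 30 lower and 4 higher (18 and 4 adjusted over the list alone; adjusted p = 5.37e-06, but adjusted p = 0.768 with an estimated correlation). Matrix genes Lama4 (-0.35 ± 0.07), Thbs2 (-0.40 ± 0.10), Bgn (-0.41 ± 0.12) and Col18a1 (-0.34 ± 0.10) fell (adjusted p = 6.02e-06, but adjusted p = 0.768 with an estimated correlation). Olfactory markers had a median of -1.57, with 1 of 18 lower (6 adjusted over the list alone; adjusted p = 5.37e-06, but adjusted p = 0.768 with an estimated correlation). In total 651 genes were higher and 775 lower, edgeR called 1418, and with the olfactory score as a covariate 302 passed (265 with a linear score). Leaving out 1 library gave 431 to 1539, and fitting only the compared libraries 4729.

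Lithium in WT mice raised many ER genes and lowered some immediate early, ribosomal protein and respiratory chain genes. The highest genes were Hif3a (0.67 ± 0.13), Crb1 (0.63 ± 0.16), Fkbp5 (0.48 ± 0.09), Cyp2s1 (0.47 ± 0.13) and Serpina3n (0.43 ± 0.12). Next were Rin3 (0.38 ± 0.10), Zbtb16 (0.38 ± 0.10), Scrt2 (0.36 ± 0.10), Klhl33 (0.35 ± 0.09) and Creb3l1 (0.35 ± 0.11). ER genes Dnajb11 (0.14 ± 0.03), Hspa5 (0.32 ± 0.06), Dnajc3 (0.16 ± 0.03) and Pdia4 (0.31 ± 0.07) rose, as did 13 of 22 of the list (17 higher and 1 lower adjusted over the list alone; adjusted p = 6.03e-15, but adjusted p = 0.0648 with an estimated correlation). The lowest genes were Arc (-0.86 ± 0.18), Junb (-0.71 ± 0.12), Npas4 (-0.70 ± 0.19), Ier2 (-0.65 ± 0.12) and Gbp4 (-0.63 ± 0.15). Next were Nr4a1 (-0.60 ± 0.11), Fos (-0.60 ± 0.16), Ccn1 (-0.58 ± 0.15), Egr4 (-0.58 ± 0.12) and Tcap (-0.57 ± 0.13). Immediate early genes had 10 of 30 lower (15 adjusted over the list alone; adjusted p = 7.28e-09, but adjusted p = 0.648 with an estimated correlation). Ribosomal protein genes Rps14 (-0.20 ± 0.04), Rpl17 (-0.25 ± 0.06), Rps15 (-0.16 ± 0.04) and Rpl13a (-0.27 ± 0.07) fell, as did 13 of 79 of the list (29 adjusted over the list alone; adjusted p = 6.03e-15, but adjusted p = 0.875 with an estimated correlation). Respiratory chain genes Ndufb4 (-0.29 ± 0.07), Cox8a (-0.23 ± 0.06), Uqcrq (-0.17 ± 0.05) and Ndufa4 (-0.22 ± 0.06) fell (adjusted p = 0.00859, but adjusted p = 0.875 with an estimated correlation). In total 357 genes were higher and 287 lower, and edgeR called 705. Fitting only the compared libraries called 122, and leaving out 1 library gave 292 to 842. Olfactory markers had a median of 0.70 with 0 of 18 passing, and 1415 genes passed with their score as a covariate.

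In HT mice lithium raised many ER genes and some respiratory chain genes and lowered some matrix genes. The highest genes were Map3k6 (0.77 ± 0.13), Serinc2 (0.71 ± 0.18), Pkp2 (0.60 ± 0.14), Hif3a (0.60 ± 0.13) and Mc4r (0.60 ± 0.19). Next were Thrsp (0.59 ± 0.10), Tnfrsf25 (0.58 ± 0.15), Smim3 (0.57 ± 0.11), Sdf2l1 (0.54 ± 0.08) and Paqr5 (0.54 ± 0.10). ER genes Pdia6 (0.30 ± 0.04), Hspa5 (0.43 ± 0.06) and Manf (0.25 ± 0.04) rose, with 14 of 22 higher (16 adjusted over the list alone; adjusted p = 1.44e-16, and adjusted p = 0.0357 with an estimated correlation). Respiratory chain genes Sdhd (0.13 ± 0.03), Cox7a2 (0.22 ± 0.05), Ndufb6 (0.24 ± 0.06) and Ndufa8 (0.12 ± 0.03) rose, with 12 of 75 higher (36 adjusted over the list alone; adjusted p = 2.40e-15, but adjusted p = 0.396 with an estimated correlation). The lowest genes were Scube3 (-1.27 ± 0.36), Aplnr (-0.93 ± 0.20), Nr4a2 (-0.79 ± 0.25), Fosb (-0.75 ± 0.19) and Ndnf (-0.73 ± 0.21). Next were Adamts5 (-0.64 ± 0.20), Frat1 (-0.64 ± 0.10), Piezo2 (-0.63 ± 0.16), Zfhx2os (-0.62 ± 0.17) and Ankfn1 (-0.62 ± 0.17). Matrix genes Col6a2 (-0.26 ± 0.06), Col18a1 (-0.44 ± 0.10), Thbs2 (-0.43 ± 0.10) and Hspg2 (-0.30 ± 0.07) fell, with 11 of 35 lower (21 adjusted over the list alone; adjusted p = 3.47e-12, but adjusted p = 0.378 with an estimated correlation). Ctnnb1, the WNT effector beta-catenin, fell in HT from 16588 ± 624 to 14489 ± 648 (-0.20 ± 0.03) and in WT from 15851 ± 909 to 14496 ± 506 (-0.13 ± 0.03). Olfactory markers had a median of -1.56 with 0 of 18 lower (17 adjusted over the list alone; adjusted p = 5.52e-07, but adjusted p = 0.438 with an estimated correlation). In total 526 genes were higher and 434 lower, edgeR called 985, and with the olfactory score as a covariate 236 passed (707 with a linear score). Leaving out 1 library gave 495 to 2087, and fitting only the compared libraries 2487.

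The response to fluoxetine differed between genotypes in 408 genes, 159 with a higher and 249 with a lower response in HT. Fkbp5 rose less in HT (0.50) than in WT (1.18), a difference of -0.68 ± 0.13 (adjusted p = 0.00507). Tnfrsf25 fell in WT (-0.87) and rose in HT (0.50), a difference of 1.37 ± 0.21 (adjusted p = 5.02e-04). Other responses higher in HT were Il11ra1 (0.38 ± 0.06), Ier5l (0.78 ± 0.13), Sox8 (0.42 ± 0.08) and Tek (0.45 ± 0.09), and lower ones Gabra5 (-0.46 ± 0.07), Clip4 (-0.29 ± 0.05), Ncl (-0.19 ± 0.04) and Eif4b (-0.19 ± 0.04). Arc (1.02 ± 0.26), which fell to 2285 ± 897 in WT and was 4246 ± 1859 in HT fluoxetine, differed too (adjusted p = 0.0271), as did Klf10 (0.72 ± 0.15). For lithium 109 genes differed, 60 higher and 49 lower in HT, led by Il11ra1 (0.40 ± 0.06), Tomm5 (0.45 ± 0.08), Triap1 (0.44 ± 0.09), Avpi1 (0.31 ± 0.06) and Tomm40l (0.27 ± 0.05) and by Eif4b (-0.19 ± 0.04), Akap9 (-0.28 ± 0.06), Lrp12 (-0.22 ± 0.05), Fbxo38 (-0.20 ± 0.04) and Cdh2 (-0.22 ± 0.05). Olfactory marker means moved by -2.06 and -2.19 in these contrasts, and with their score as a covariate 39 and 1 genes passed (325 and 101 with a linear score). On leaving out 1 library at a time the fluoxetine count ran from 161 to 1300, and it was 102 without the libraries that stand apart and 1039 with array weights. The lithium count ran from 6 to 847, and it was 61 with a replicate block and 9 without the libraries that stand apart. No gene list kept its call with an estimated correlation in either interaction.

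Split by sex, the genotype difference in vehicle had 2341 genes higher and 2204 lower in females, and 103 and 91 in males, with 5 libraries per group. Olfactory markers differed by 3.22 in females and 0.96 in males. The female count of 4545 was 2590 with the olfactory score as a covariate, of which 1332 were among the 4545, and 6875 with array weights, and ran from 3230 to 4383 on leaving out 1 library at a time. The male count of 194 ran from 5 to 738 on leaving out 1 library at a time, and was 17 when only the compared libraries were fitted, 532 with the olfactory score, 1597 with a linear score and 973 with array weights. Genes called in both sexes numbered 83 higher and 65 lower. Fluoxetine raised 275 and lowered 216 genes in WT females, 225 and 212 in WT males, 27 and 46 in HT females and 48 and 21 in HT males. Leaving out 1 library gave 154 to 780 in WT females, 149 to 2976 in WT males, 28 to 89 in HT females and 19 to 84 in HT males. Fitting only the compared libraries gave 225, 9, 249 and 2827. In WT females the balance turned with the olfactory score as a covariate (120 higher, 206 lower) and with a linear score (260, 289). It also turned there without the libraries that stand apart (63, 92). Of 100 splits of the libraries 9 had as many genes as WT males. Lithium raised 247 and lowered 162 genes in WT females, 5 and 5 in WT males, 600 and 526 in HT females and 4 and 1 in HT males. Leaving out 1 library gave 66 to 849 in WT females, 0 to 27 in WT males, 106 to 2596 in HT females and 0 to 19 in HT males, and fitting only the compared libraries gave 1, 0, 3262 and 0. For lithium in WT males edgeR called 52, array weights 35, and the olfactory and linear scores 58 and 147. For lithium in HT males these were 7, 188, 23 and 67. Tested directly with limma and equal weights, no gene was called for a different response between the sexes in these 5 comparisons. With 5 libraries per group this does not show that the responses were equal. Array weights called 4640 genes for fluoxetine in WT and 1609 for lithium in HT, and leaving out WT fluoxetine male replicate 2 gave 3260 for fluoxetine in WT. Those tests had 1112, 3542, 670, 1297 and 1485 genes with p under 0.05 before adjustment, and edgeR called 0 in each.

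Across the 16659 genes, fluoxetine effects in WT and HT had a Pearson correlation of -0.08 (Spearman 0.03), and lithium effects -0.17 (-0.02). Genes are not independent replicates, so each correlation was compared with 100 splits of libraries, and 48 and 32 of these were as extreme. Both turned positive with the olfactory score as a covariate (0.20 and 0.11), and the fluoxetine one also without the libraries that stand apart (0.059), so no direction was settled. Genes called in both genotypes numbered 80 higher and 98 lower for fluoxetine, where 18.3 and 24.6 would be expected by chance, and 61 and 18 for lithium, where 11.3 and 7.48 would be expected. Genotype effects in vehicle correlated at 0.33 (0.36) with those under fluoxetine and at 0.24 (0.32) with those under lithium, with 40 and 56 of 100 splits as extreme. With the olfactory score as a covariate these were 0.53 and 0.44. Genes called in vehicle and under fluoxetine numbered 676 higher and 398 lower in both, where 210 and 144 would be expected by chance, and 21 and 10 ran opposite. In vehicle and under lithium they numbered 96 and 41, where 21.1 and 11.6 would be expected, and 0 and 2 ran opposite. The genotype effect in vehicle ran opposite to the drug effect in HT, at -0.66 (-0.53) for fluoxetine and -0.73 (-0.58) for lithium, and 1 of 100 splits, the real one, was as extreme for each. Both sides of that comparison use the HT vehicle libraries, and simulated data without any effect gave means of -0.49 (range -0.72 to -0.15) and -0.47 (-0.77 to -0.07), ranges that hold both observed values. The splits regrouped only the drug contrast, so the real split alone set all HT vehicle libraries on opposite sides. That favours a negative value, so the count of splits cannot decide here. The observed covariances were -0.0422 and -0.0447, against simulated means of -0.00625 and -0.00649 and lowest values of -0.0156 and -0.0168. With separate HT vehicle libraries on each side the values were -0.51 and -0.57. With shared libraries and the olfactory score as a covariate they were -0.29 and -0.46. Fluoxetine in WT against lithium in HT gave -0.12 (0.02), and fluoxetine in HT against lithium in WT -0.23 (-0.12), with 38 and 61 of 100 splits as extreme. These turned positive with the olfactory score too (0.11 and 0.047).

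Female and male effects correlated at 0.63 (Spearman 0.65) for genotype in vehicle and at 0.58 (0.56) for fluoxetine in HT, with 2 and 1 of 100 splits as extreme. After Benjamini-Hochberg adjustment over the 13 correlations these shares of splits were 0.065 and 0.043, so only that for fluoxetine in HT stayed below 0.05. For fluoxetine in WT the correlation was -0.27, for lithium in WT 0.03 and for lithium in HT 0.42, with 61, 96 and 22 of 100 splits as extreme. With the olfactory score as a covariate they were 0.27, 0.19 and 0.15, so the first turned direction, and fluoxetine in HT went from 0.58 to 0.30. These were again correlations over genes that are not independent replicates.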

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

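The olfactory marker covariates, the neuron-share comparison and the criteria for the 5 olfactory tests were chosen after the results were seen, and the library checks, splits and GC and depth tests before.

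Single libraries lay apart from the other 4 of their group on 15 of 156 checks (13 measures in 12 groups), where 7.80 would be expected by chance, because about 1 in 20 groups is picked out when nothing differs. Recovered reads were 23.6 M in WT lithium female replicate 1, against 31.4 to 34.5 in the other 4. The mitochondrial share was 7.97% in HT lithium male replicate 3 (others 6.94 to 7.18) and 6.72% in WT lithium male replicate 3 (others 7.52 to 7.79). Pten was 7547 in HT fluoxetine female replicate 2, against 7343 to 7378. Olfactory markers were 8.22 in WT vehicle female replicate 4, against 5.62 to 6.08. Striatal markers were 9.99 in HT vehicle female replicate 3 (others 7.93 to 8.08), 8.25 in HT fluoxetine female replicate 5 (others 7.96 to 8.02) and 7.91 in HT lithium male replicate 1 (others 8.02 to 8.05). Thalamic and hypothalamic markers were 9.56 in WT lithium male replicate 1 (others 7.66 to 8.16) and 7.68 in HT fluoxetine male replicate 5 (others 7.99 to 8.10). Septal markers were 6.59 in HT lithium female replicate 5, against 5.90 to 6.09.

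The mean of ER stress genes was 10.68 in HT fluoxetine female replicate 4 (others 10.80 to 10.85), 10.87 in HT fluoxetine male replicate 3 (others 10.74 to 10.77) and 10.62 in WT vehicle female replicate 1 (others 10.65 to 10.66). Glucocorticoid-responsive genes averaged 9.75 in WT fluoxetine male replicate 2, against 9.49 to 9.55. By a rule chosen after seeing the data, 4 libraries lay over 1 log2 above their group median in a list of striatum, thalamus, septum or choroid plexus, while the olfactory list was not searched: HT vehicle female replicate 3 and HT fluoxetine male replicate 4 in striatum (9.99 against 8.04, and 9.62 against 8.08), WT lithium male replicate 1 in thalamus (9.56 against 8.13) and WT fluoxetine female replicate 4 in choroid plexus (8.21 against 5.89).

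Responses that differed between the genotypes numbered 408 genes for fluoxetine and 109 for lithium. For fluoxetine the difference was 1.37 for Tnfrsf25, 0.38 for Il11ra1, 0.78 for Ier5l, 0.42 for Sox8 and 0.45 for Tek, and -0.46 for Gabra5, -0.29 for Clip4, -0.19 for Ncl, -0.68 for Fkbp5 and -0.19 for Eif4b. For lithium it was 0.40 for Il11ra1, 0.45 for Tomm5, 0.44 for Triap1, 0.31 for Avpi1 and 0.27 for Tomm40l, and -0.19 for Eif4b, -0.28 for Akap9, -0.22 for Lrp12, -0.20 for Fbxo38 and -0.22 for Cdh2. Gene list calls in the interactions are left aside because none stayed with an estimated correlation.

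In each of 24 comparisons the called genes were counted in 100 splits of the libraries, the real one included. Only the real split reached its count in 14 of 19 comparisons with called genes. These were genotype in vehicle (5210, highest other 1) and under fluoxetine (2247, 36), fluoxetine in HT (1426, 1), lithium in WT (644, 315) and HT (960, 1), and the lithium interaction (109, 1). In females they were genotype in vehicle (4545, 3), fluoxetine in WT (491, 18) and HT (73, 2), and lithium in WT (409, 61) and HT (1126, 540). In males they were genotype in vehicle (194, 15), fluoxetine in HT (69, 0) and lithium in HT (5, 3). In some of these 14 no other split held as large an olfactory marker difference as the real one. These were genotype in vehicle (2.09), fluoxetine and lithium in HT (-1.34 and -1.48), genotype in vehicle females (3.22) and fluoxetine in HT males (-1.66). The splits cannot tell an effect of genotype or drug from olfactory share there. In the rest another split held a larger difference. Each drug reached the pups through the dam, and litters were not named. In the drug comparisons a difference between litters could also set the real split apart, so the splits cannot tell it from a drug effect. Other counts were reached by more splits: 4 of 100 for genotype under lithium (207, highest other 1448), 4 for fluoxetine in WT (997, 4200), 2 for the fluoxetine interaction (408, 878), 3 for lithium in WT males (10, 876) and 9 for fluoxetine in WT males (437, 6857). By the rule set beforehand, at least 5 of 100 splits, chance was kept only for fluoxetine in WT males. In each of these comparisons, however, another split gave a higher count than the real one, so chance was not excluded for any of them. Those highest splits held olfactory marker differences of -1.68, 2.14, -2.35, -1.96 and 3.06.

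The 5 sex differences with 0 called genes were reached by all 100 splits, and their highest other counts were 33 for genotype in vehicle, 6226 and 1 for fluoxetine in WT and HT, and 35 and 302 for lithium in WT and HT. limma gave 1112, 3542, 670, 1297 and 1485 genes with p under 0.05 before adjustment there, and edgeR called 0 in each.

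A larger share of olfactory tissue in the HT vehicle dissections may account for part of the 5210 genotype differences in vehicle, where olfactory markers were 2.09 higher on the log2 scale in HT. With their score as a covariate 2519 of the 5210 genes still passed (3581 with a linear score), and 4973 kept their sign (all 5210 with a linear score). The median absolute fold change went from 0.22 to 0.13 while the median standard error went from 0.06 to 0.05, so the calls ended because the fold changes shrank. GC content and length, and sequencing depth, were excluded as the whole cause: 5196 genes passed after removal of GC and length trends and 5217 with depth as a covariate (4231 and 5162 of the same genes). Of 100 splits 1, the real one, reached 5210, but no other split held as large an olfactory difference. In the fluoxetine interaction 35 of 408 genes still passed (90 with a linear score) and the median fold change went from 0.29 to 0.19 (0.17), so olfactory share may account for many of these calls, but all 408 kept their sign and 325 genes passed in all with the linear score, 235 of them new. In the lithium interaction 1 of 109 did (63 with a linear score) while all 109 kept their sign and the median fold change went from 0.27 to 0.19 (0.22), so the 2 scales part and the test cannot decide. An effect of the knock-in on the olfactory regions themselves was not tested and would look the same in these libraries.

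Higher oligodendrocyte transcripts in HT could come from a difference in tissue share instead of myelination. With the olfactory score as a covariate the vehicle median of mature oligodendrocyte genes was 0.829, against 0.93 without it, so olfactory tissue was excluded as the cause. A lower share of neurons would raise all glial and vascular genes, but the highest median among astrocyte, microglia and endothelial lists was 0.00908 in vehicle, 0.169 under fluoxetine and 0.0907 under lithium, and 1 of 100 splits, the real one, gave an oligodendrocyte median as large. The 28 of 30 genes called in vehicle, 27 under fluoxetine and 20 under lithium make a larger or earlier oligodendrocyte population in HT a hypothesis that could be tested by cell counts. More white matter in HT dissections would raise the same genes, was not tested and stays open. Striatal markers, which more striatum would raise, had medians of 0.15 in vehicle and 0.02 under lithium (74 and 69 of 100 splits as extreme) and 0.30 under fluoxetine (1 of 100), against 0.93, 0.69 and 1.10 for mature oligodendrocyte genes. Deep-layer neuron genes averaged higher in HT than in WT in vehicle (9.83 against 9.43), fluoxetine (9.86 against 9.61) and lithium (9.74 against 9.55). Upper-layer genes averaged lower in HT in the same order (11.10 against 11.26, 11.19 against 11.25 and 11.158 against 11.215). Whether these shifts mark a difference in dissection was not tested. Mature oligodendrocyte genes averaged 10.95 in WT vehicle male replicate 5, within the 10.38 to 11.01 of HT vehicle libraries. In its group that library was also highest in deep-layer genes (9.87) and lowest in upper-layer genes (10.96). WT vehicle female replicate 5 was highest of its group in mature oligodendrocyte genes (9.99) but lowest in deep-layer genes. Whether these lists move together over all libraries was not tested.

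Higher ER chaperones after both drugs might have reflected the tissue share or the vehicle libraries that both drugs were compared with. With the olfactory score as a covariate the lowest of the 4 medians was 0.138, and the 4 medians were 0.21, 0.20, 0.14 and 0.15 (0.20, 0.19, 0.13 and 0.15 without it), so olfactory share was excluded. Shared vehicle libraries were excluded too, because fluoxetine in WT and lithium in HT share no library and for each 1 of 100 splits, the real one, gave a list median as high. With an estimated correlation 3 of the 4 list calls stayed. A drug-induced or maternal stress response remains a hypothesis, because pups of 1 dam share her milk and litters were not named.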

How the results depend on the processing

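The olfactory covariates and the exclusion of libraries that stand apart were chosen after the results were seen, and the other alternatives before. They covered 24 counts, 13 correlations, 177 list calls and 927 gene results. Counts were held against a 1.5-fold change, and correlations against the standard deviation of the same correlation among other splits. Without the gene filter and with a pseudocount of 5 no count changed by over 1.5-fold and no correlation moved beyond that spread. The correlation of the sexes for lithium in WT went from 0.025 to 0.0093 and 0.055.

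With the olfactory score as a covariate the count was 3646 for genotype under fluoxetine, 664 for genotype under lithium, 2206 and 302 for fluoxetine in WT and HT, 1415 and 236 for lithium in WT and HT, and 39 and 1 for the fluoxetine and lithium interactions. In females it was 2590 for genotype in vehicle, 326 for fluoxetine in WT and 88 for lithium in HT. In males it was 532 for genotype in vehicle, 29 for fluoxetine in HT, and 58 and 23 for lithium in WT and HT. Correlations were 0.20 between the genotypes for fluoxetine, 0.11 for lithium, 0.11 for fluoxetine in WT with lithium in HT, -0.29 for genotype with fluoxetine in HT and 0.27 between the sexes for fluoxetine in WT. Signs turned for genotype in vehicle in Tbx21 (-0.14), Doc2g (-0.14), Dnah11 (-0.092), Scgn (-0.39), Frmd7 (-0.20) and Calb2 (-0.039), in the lithium interaction in Ldha (-0.0047), Dlx2 (0.021) and Dlx5 (0.075), and in Pten for fluoxetine in HT (-0.0152). Turned lists had adjusted p in limma of 0.942 for neuroblast and 0.826 for olfactory genes in genotype in vehicle, 0.775 and 0.699 for olfactory genes with fluoxetine and lithium in WT, and 0.988 for neuroblast genes with lithium in HT. Neuroblast genes had 0.964 and 0.998 in the fluoxetine and lithium interactions, and olfactory genes 0.832 in the latter. The covariate removes what moves with these markers, as its construction sets.

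With a linear olfactory score the count was 3820 and 1269 for genotype under fluoxetine and lithium, 2928 and 265 for fluoxetine in WT and HT, and 1994 for lithium in WT. In females it was 816 and 603 for lithium in WT and HT, and in males 1597 for genotype in vehicle, 877 and 30 for fluoxetine in WT and HT, and 147 and 67 for lithium in WT and HT. The 4 correlations that moved beyond the spread of other splits were 0.13 (fluoxetine, WT with HT), 0.043 (lithium, WT with HT), 0.11 (fluoxetine in WT with lithium in HT) and 0.20 (between the sexes, fluoxetine in WT). Within that spread, fluoxetine in HT with lithium in WT went from -0.23 to 0.015, genotype with fluoxetine in HT from -0.66 to -0.36, and the sexes from 0.58 to 0.29 for fluoxetine in HT and from 0.42 to 0.18 for lithium in HT. Signs turned in the fluoxetine interaction for Dlx6 (0.057), Dlx5 (0.042), Zic1 (0.11) and Prokr2 (0.082), and for Pten in fluoxetine in HT (-0.0321). Lists that turned with fluoxetine in HT had adjusted p in limma of 0.586 (glutamate receptors), 0.00948 (presynaptic), 0.586 (neuroblast) and 0.646 (olfactory). In the fluoxetine interaction they were 0.840 (cholesterol), 0.395 (neuroblast) and 0.971 (olfactory).

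Fitting only the compared libraries gave 1264 for genotype under fluoxetine, 349 and 4729 for fluoxetine in WT and HT, 122 and 2487 for lithium in WT and HT and 336 for the lithium interaction. In females the count was 225 and 249 for fluoxetine in WT and HT and 1 and 3262 for lithium in WT and HT. In males it was 17 for genotype in vehicle, 9 and 2827 for fluoxetine in WT and HT, and 0 and 0 for lithium in WT and HT. Here the spread came from those groups alone, and olfactory markers varied least in HT vehicle.

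Array weights gave 593 for genotype under lithium, 2002 and 3908 for fluoxetine in WT and HT, 3638 for lithium in HT, and 1039 and 956 for the interactions. In females the counts were 6875 for genotype in vehicle, 2264 and 618 for fluoxetine in WT and HT, and 649 and 5884 for lithium in WT and HT. Male counts were 973 for genotype in vehicle, 3952 and 1863 for fluoxetine in WT and HT, and 35 and 188 for lithium in WT and HT. Sex differences had 4640 genes for fluoxetine in WT and 1609 for lithium in HT, and the cause was not tested.

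Without the 4 libraries that stand apart the count was 948 for fluoxetine in HT, 102 and 9 for the interactions, 155 for fluoxetine in WT females, 498 for lithium in HT females, 18 for fluoxetine in HT males and 0 for lithium in WT males. Correlations were 0.059 for fluoxetine in WT with HT and 0.0019 for fluoxetine in WT with lithium in HT. The cause was not tested.

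Quantile normalization gave 322 for the lithium interaction, 240 for fluoxetine in WT males, 18 for lithium in WT males and 10 for lithium in HT males. The median fold change moved by at most 0.02 in any contrast, while genotype in vehicle went from 2729 higher and 2481 lower to 2589 and 3020, and in females from 2341 and 2204 to 2319 and 2655. Genotype in vehicle males went from 103 higher and 91 lower to 100 and 149, and lithium in WT males from 5 and 5 to 6 and 12. Signs turned for mt-Nd2 (0.0013), mt-Cytb (0.0275) and mt-Nd1 (0.11) in genotype in vehicle, mt-Nd1 (0.0456) in genotype under fluoxetine and mt-Nd2 (-0.0267) with fluoxetine in HT. They also turned for mt-Nd1 (0.0695) and mt-Cytb (0.0137) with lithium in WT, mt-Cytb (-0.0137) in the lithium interaction and Pten (-0.0522) with fluoxetine in HT. edgeR on recovered reads gave 52 for lithium in WT males (37 higher, 15 lower). The cause was not tested.

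A replicate block gave 61 for the lithium interaction and 9 for lithium in HT males, and all 177 list calls stayed. Residuals of libraries with the same replicate number correlated at 0.0082 and of others at -0.0021, 15 of 60 libraries were closest to their own number, and 11 of 66 group pairs had a mean over 0.1. The cause was not tested.

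With an estimated correlation 6 of 177 list calls stayed and 171 were lost, because genes of a list vary together between libraries.

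Leaving out 1 library at a time, the count for genotype under lithium (207) ran from 79 to 263. Numbers after a group are its replicates. It was 79 and 130 without HT lithium female 4 and 5 and 91 without HT lithium male 2. It was 109 and 101 without WT lithium female 1 and 3 and 123 without WT lithium male 5. Fluoxetine in HT (1426) ranged from 431 to 1539. It was 928, 865 and 610 without HT fluoxetine female 1, 2 and 4 and 885 and 514 without HT fluoxetine male 4 and 5. It was 431 without HT vehicle female 2 and 573 without HT vehicle male 4. Lithium in WT (644) ran from 292 to 842. It was 425 and 292 without WT lithium female 2 and 5 and 409 without WT lithium male 5. It was 366 without WT vehicle female 5. Lithium in HT (960) ranged from 495 to 2087. It was 582, 614 and 2087 without HT lithium female 2, 4 and 5 and 579 and 495 without HT lithium male 3 and 5. It was 512 without HT vehicle female 2 and 572 without HT vehicle male 4.

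The fluoxetine interaction (408) ran from 161 to 1300. It was 189 without HT fluoxetine female 4 and 255 and 222 without HT fluoxetine male 4 and 5. It was 199 without HT vehicle female 2 and 247 without HT vehicle male 4. It was 671 and 161 without WT fluoxetine female 1 and 4 and 211, 1300 and 243 without WT fluoxetine male 2, 4 and 5. It was 205 without WT vehicle female 5 and 629 and 202 without WT vehicle male 1 and 2. The lithium interaction (109) ranged from 6 to 847. It was 13, 48, 11, 52 and 765 without HT lithium female 1, 2, 3, 4 and 5 and 495, 53, 8, 230 and 19 without HT lithium male 1, 2, 3, 4 and 5. It was 200, 9 and 14 without HT vehicle female 1, 2 and 3 and 201, 65, 10 and 44 without HT vehicle male 2, 3, 4 and 5. It was 716, 6, 847, 20 and 47 without WT lithium female 1, 2, 3, 4 and 5 and 58, 49, 174, 326 and 47 without WT lithium male 1, 2, 3, 4 and 5. It was 47, 71 and 38 without WT vehicle female 2, 3 and 5 and 10 and 56 without WT vehicle male 2 and 4. Fluoxetine in WT females (491) ran from 154 to 780. It was 780, 174, 759 and 154 without WT fluoxetine female 1, 2, 3 and 4 and 296, 325 and 181 without WT vehicle female 2, 3 and 5. Fluoxetine in HT females (73) ranged from 28 to 89. It was 47 and 43 without HT fluoxetine female 1 and 2 and 28 and 40 without HT vehicle female 2 and 3.

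Lithium in WT females (409) ran from 66 to 849. It was 845, 66, 849, 184 and 75 without WT lithium female 1, 2, 3, 4 and 5 and 133, 253 and 132 without WT vehicle female 2, 4 and 5. Lithium in HT females (1126) ranged from 106 to 2596. It was 592, 340, 329, 234 and 2596 without HT lithium female 1, 2, 3, 4 and 5 and 106, 422 and 683 without HT vehicle female 2, 3 and 5. Genotype in vehicle males (194) ran from 5 to 738. It was 5, 124, 37 and 36 without HT vehicle male 2, 3, 4 and 5 and 13, 67, 62, 22 and 738 without WT vehicle male 1, 2, 3, 4 and 5. Fluoxetine in WT males (437) ranged from 149 to 2976. It was 149, 2976, 279 and 234 without WT fluoxetine male 1, 2, 3 and 5 and 186, 1072, 166 and 253 without WT vehicle male 1, 2, 4 and 5.

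Fluoxetine in HT males (69) ran from 19 to 84. It was 19, 19 and 35 without HT fluoxetine male 2, 4 and 5 and 20, 41 and 21 without HT vehicle male 1, 2 and 4. Lithium in WT males (10) ranged from 0 to 27. It was 1, 21 and 5 without WT lithium male 1, 2 and 3 and 6, 27, 0, 0 and 5 without WT vehicle male 1, 2, 3, 4 and 5. Lithium in HT males (5) ran from 0 to 19. It was 19, 3, 0, 1 and 0 without HT lithium male 1, 2, 3, 4 and 5 and 0, 1 and 3 without HT vehicle male 1, 4 and 5. The sex difference of fluoxetine in WT (0) ranged from 0 to 3260. It was 3260 without WT fluoxetine male 2 and 1 without WT vehicle female 2. It was 1 without WT vehicle male 2.

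The correlation of fluoxetine in WT with fluoxetine in HT (-0.08) ran from -0.21 to 0.151. It was -0.21 and 0.0435 without WT fluoxetine female 3 and 4 and 0.15 without WT fluoxetine male 2. It was 0.11 without WT vehicle male 2. The correlation of lithium in WT with lithium in HT (-0.17) ran from -0.27 to 0.0163. It was -0.0219 without WT lithium female 2 and 0.0163 without WT vehicle male 2. The correlation of fluoxetine in WT with lithium in HT (-0.12) ran from -0.25 to 0.0934. It was -0.25 and -0.00770 without WT fluoxetine female 3 and 4 and 0.0934 without WT fluoxetine male 2. It was 0.0632 without WT vehicle male 2.

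Pten with fluoxetine in HT ran from -0.00081 to 0.0193. Ranges without a change over 1.5-fold were 4479 to 5411 for genotype in vehicle, 3230 to 4383 for genotype in vehicle females (4545 with all libraries), 1654 to 2659 for genotype under fluoxetine and 681 to 1420 for fluoxetine in WT. The cause of the moves on leaving out libraries was not tested.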

Other observations

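All tests in this part were planned before the results were seen, except the marker score covariates and the comparison of the main residual axis with the olfactory score.

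Some immune and vascular genes fell in WT after fluoxetine, and none of their lists kept its call with an estimated correlation. Antigen presentation genes H2-Q4 (-0.62 ± 0.13), H2-Q7 (-0.88 ± 0.22), Tap1 (-0.39 ± 0.11) and Psmb8 (-0.41 ± 0.12) fell (log2 fold change ± standard error from limma, n = 10), with 4 of 17 lower (9 adjusted over the list alone; adjusted p = 7.44e-08, but adjusted p = 0.225 with an estimated correlation). Interferon-induced genes Parp14 (-0.47 ± 0.12), Irf9 (-0.28 ± 0.07) and Gbp2 (-0.53 ± 0.15) fell, with 3 of 29 lower (7 adjusted over the list alone; adjusted p = 1.75e-06, but adjusted p = 0.518 with an estimated correlation). Pericyte genes Pdgfrb (-0.27 ± 0.04), Atp13a5 (-0.23 ± 0.05), Des (-0.47 ± 0.12) and Ndufa4l2 (-0.40 ± 0.11) fell (adjusted p = 1.79e-06, but adjusted p = 0.216 with an estimated correlation). WNT target genes Nkd1 (-0.30 ± 0.05), Dkk2 (-0.70 ± 0.14), Tnfrsf19 (-0.25 ± 0.06) and Notum (-0.36 ± 0.09) fell (adjusted p = 3.70e-04, but adjusted p = 0.134 with an estimated correlation). In HT the pericyte gene Pdgfrb fell by 0.15 with fluoxetine and by 0.19 with lithium, but antigen presentation and interferon lists passed for neither.

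Several genes induced by glucocorticoids rose with the drugs, but their list was mixed. Map3k6 rose with fluoxetine in WT (0.89 ± 0.13) and HT (0.88 ± 0.13) and with lithium in HT (0.77 ± 0.13), and Zbtb16 rose in all 4 comparisons, from 0.38 ± 0.10 with lithium in WT to 0.87 ± 0.10 with fluoxetine in WT. Fkbp5 rose with fluoxetine in WT (1.18 ± 0.09) and HT (0.50 ± 0.09) and with lithium in WT (0.48 ± 0.09). In HT with lithium Tsc22d3 (0.50 ± 0.09) and Mertk (0.31 ± 0.07) rose, and the list had 5 of 24 higher (9 adjusted over the list alone; adjusted p = 4.90e-05, but adjusted p = 0.396 with an estimated correlation). Fluoxetine in WT gave 8 higher and 5 lower (10 and 6 adjusted over the list alone; adjusted p = 0.0446, but adjusted p = 0.736 with an estimated correlation). Fluoxetine in HT gave 8 higher and 2 lower (9 and 4 adjusted over the list alone; adjusted p = 0.0301, but adjusted p = 0.768 with an estimated correlation). Lithium in WT gave 2 higher and 2 lower (4 and 7 adjusted over the list alone), and the list did not pass (adjusted p = 0.530 in limma). With fluoxetine in WT, Dusp1 and Per1, which are also immediate early genes, were among the lower ones.

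Lists that passed in none of the 9 contrasts averaged over sex were choroid plexus (smallest adjusted p = 0.0968 in limma), parvalbumin and somatostatin interneurons (0.0870), GABA receptors (0.124), serotonin receptors (0.111), erythroid genes (0.123), VIP interneurons (0.135) and FOXO targets (0.142).

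After the 12 group means were removed, the first residual component held 28.2% of the variance and the second 5.66%. The first correlated with the olfactory score over the 60 libraries at 0.963 (Spearman 0.958), with a permutation p of 1e-04, the smallest that 10000 permutations can give, and at 0.957 without the 2 farthest libraries. The main axis along which libraries of 1 group differed thus followed the olfactory markers. The genes of that score were among those that formed the component, and the comparison was chosen after seeing the data. Component and score were therefore not independent, and the permutation p adds no separate evidence.

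Whether the oligodendrocyte difference reflects white matter in the dissection would be tested by counting oligodendrocytes in sections of a fixed cortical area in HT and WT. Myelin proteins in cortex freed of white matter and olfactory tissue would separate the same explanations, and naming litters would show how far pups of 1 dam move together.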
